A study of Mus musculus with 24 samples.

How the data were processed

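Long RNA and small RNA libraries were made by the study from total RNA of the liver, extracted with TRIzol, of 12 mice, 4 per group. The labels give a stranded total RNA kit with removal of ribosomal RNA for long RNA, and adapter ligation, reverse transcription and PCR for small RNA. The deposited tables hold whole-number counts per gene and per mature miRNA, made by the authors, whose notes name HISAT2, RSEM and the mouse build GRCm39. The versions and roles of these tools, the step that counted the reads, the miRNA reference and the rule by which genes were listed are not given in the sources used here. All values were whole numbers from 0, and no normalization had been applied. Of the 18314 long RNA entries, 18227 had Ensembl IDs and 87 were assembled loci without one, 15 symbols stood for more than 1 entry, and 25 entries had no count. Of 18227 IDs, 18160 were found in the reference list of gene names and 17270 had the same symbol there. Among 1291 miRNA entries 107 lacked the mouse prefix. The members of 5 sets of miRNAs had identical counts in all libraries (miR-199a-3p and 199b-3p, 486a-5p and 486b-5p, let-7a-1-3p and let-7c-2-3p, 299a-5p and 299b-5p, and 465a-3p, 465b-3p and 465c-3p). No library was a copy of another.

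Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (version 1.17.8), and figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6. Low counts were removed with filterByExpr by group, which left 13929 genes and 414 miRNAs for 12 mice and 13832 genes and 406 miRNAs for 10 mice. Libraries were scaled by TMM, whose factors ran from 0.698 to 1.55 for long RNA and from 0.606 to 2.2 for small RNA with 12 mice, and from 0.763 to 1.42 and 0.707 to 1.61 with 10. One quasi-likelihood model per assay held the means of the 3 groups (estimateDisp, robust glmQLFit and glmQLFTest), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of F. Each mouse has its own batch code in the labels, so no batch term could be fitted. The 3 comparisons were HFD against control, HFD plus HQHF against HFD, and HFD plus HQHF against control.

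Gene lists and cell type lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the first set of other settings. They cover ferroptosis drivers, ferroptosis suppressors, iron handling, lipogenesis, fatty acid oxidation and PPARA targets, lipid uptake and droplets, cholesterol synthesis, bile acid and sterol disposal, glucose output and insulin response, antioxidant and NRF2 targets, ER stress and ATF4, xenobiotic metabolism, cytokines and acute phase, interferon response, matrix and fibrosis, cell cycle, circadian clock, male-biased and female-biased liver genes, and mitochondrially encoded genes. The cell types are hepatocyte, Kupffer cell, monocyte and recruited macrophage, endothelial cell, stellate cell, cholangiocyte, T and NK cell, B and plasma cell, neutrophil, red blood cell, adipocyte and pancreatic acinar cell. Lists with at least 5 tested members were tested with camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, which left out the adipocyte and acinar lists, so 30 were tested and adjusted together. The 6 miRNA lists (hepatocyte, steatosis-linked, immune cell, stellate and fibrosis, miR-200 family, red blood cell) needed at least 4 members. Each list's members past the gene test were counted over all genes and adjusted over the list alone.

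In each long RNA comparison the named genes were the 6 highest and 6 lowest log2 fold changes among called genes with an ordinary symbol, a mean of at least 1 CPM in the higher group and no overlap between groups. To them came the 2 members with the smallest p of each called list and always of the ferroptosis and iron lists, and always Gpx4, Slc7a11, Acsl4, Tfrc, Fth1, Hmox1, Fasn, Scd1, Cd36, Cpt1a and Cyp7a1. For miRNAs they were the 5 highest and 5 lowest called with a mean of at least 10 CPM in the higher group, and always miR-122-5p, miR-34a-5p and miR-21a-5p. Where nothing was called, the 5 with the smallest p were given as values. A gene with no read in a group was given a bound against 3 reads over the group, and one with 1 to 3 reads a ratio with its exact 95% counting interval.

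After the data were seen, 1 alternative set of libraries was added, the 10 mice without control 2 and HFD plus HQHF 3, and each of the other settings was run on it too, together with scaling by library totals without TMM. Genes, lists, miRNAs and miRNA lists were thus fitted on 2 sets of libraries, and the 12-mouse results stand as designed. The other settings were DESeq2's Wald test, RLE scaling, no filter, a filter of at least 1 CPM in at least 4 libraries, only the libraries of the 2 groups compared, the replicate number as a block, a 2-fold minimum, an adjusted p under 0.1, leaving out each library in turn, and for lists an estimated correlation and fry. Library summaries were compared with exact two-sided permutation tests of group means, and the correlation over mice used 100000 permutations.

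The pipeline was tested on simulated HFD and control counts with known changes. With 12 mice edgeR recovered 0 of 97 genes changed by 1 on the log2 scale and 18 of 98 changed by 2, with 1 false call. With 10 mice it recovered 37 of 100 and 76 of 99, with 6 false calls, while DESeq2 made 53 false calls with 12 mice and 37 with 10. For miRNAs it recovered 1 of 19 and 4 of 20 with 12 mice and 8 of 20 and 11 of 20 with 10, with 0 false calls. The shifted list was always called, with 0 other lists, but other splits of the real mice called up to 20. The common biological coefficient of variation was 0.666 for long RNA with 12 mice and 0.314 with 10, and 0.72 and 0.476 for small RNA.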

Results

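Liver RNA of 12 male C57BL/6 mice was sequenced as long RNA and as small RNA, which gave 24 libraries. The mice fell into 3 groups of 4. Control mice ate a normal diet and HFD mice ate a high-fat diet, a common way to bring about fatty liver in mice. HFD plus HQHF mice ate the high-fat diet and received HQHF, the Huatanqushihuoxue Formula, a herbal preparation given by gavage after 12 weeks of the diet. The study kept 9 mice per group, and the labels do not give the dose of HQHF behind these libraries. Total counts ran from 33380900 in control 2 to 46454400 in HFD 4 for long RNA, and from 8139110 in control 1 to 12813800 in HFD 1 for small RNA. The tables listed 18314 genes and 1291 miRNAs. Intervals and lower bounds given for single genes cover counting error only. The values are levels relative to the other RNAs of a library, in CPM (counts scaled to a common library size).

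Control 2 and HFD plus HQHF 3 stood apart from the other 10 mice in both kinds of library. Alb, which encodes albumin, the main protein that liver cells secrete, was at 46.4 CPM in control 2 and 0.743 CPM in HFD plus HQHF 3, beside 35054 to 92208 CPM in the other 10. Adipoq, the hormone gene of fat cells, was at 4543 and 1254 CPM, beside at most 41.2 CPM. Control 2 also held 160 CPM of Lep, 1228 CPM of Retn and 6433 CPM of Cfd, which fat cells express. HFD plus HQHF 3 held 4036 CPM of Ucp1, 2104 CPM of Cidea and 565 CPM of Cox7a1, genes typical of brown fat. The hepatocyte list made up 0.00612% and 0.00151% of their counts, against 8.23% to 15.2% in the other 10, and the adipocyte list 2.21% and 0.634%, against 0.00901% to 0.133%. Clec4f, a receptor of liver-resident macrophages, had no read in either library, which allows up to 3 reads of each total, and lay between 61.5 and 158 CPM elsewhere. In the small RNA libraries of these 2 mice, miR-122-5p, the most abundant miRNA of liver cells, was at 316 and 134 CPM, against 333060 to 548310 CPM.

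Other libraries held smaller amounts of RNA from other tissues. Control 1 held 593 CPM of Pnlip, 362 CPM of Cela1, 306 CPM of Prss2 and 152 CPM of Ctrb1, digestive enzymes of the pancreas. Its acinar list made up 0.381% of counts, beside at most 0.00379% in any other library. HFD 3 held 41.2 CPM of Adipoq, 32.0 CPM of Plin1 and 60.0 CPM of Cidea. Without Car3, which liver expresses too and which was split off after its values were seen, the adipocyte list made up 0.0169% of its counts, against at most 0.000664% in the other 9 mice with hepatocyte RNA. In HFD 1, where the whole list was at 0.133%, it was then 0.000149%. Because control 2 and HFD plus HQHF 3 held almost no hepatocyte RNA, every comparison was also run on the other 10 mice, an alternative added after the data were seen. The 12-mouse results come first as the design fixed them, and the 10-mouse results follow. Both are given for each comparison.

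**Figure D1:**
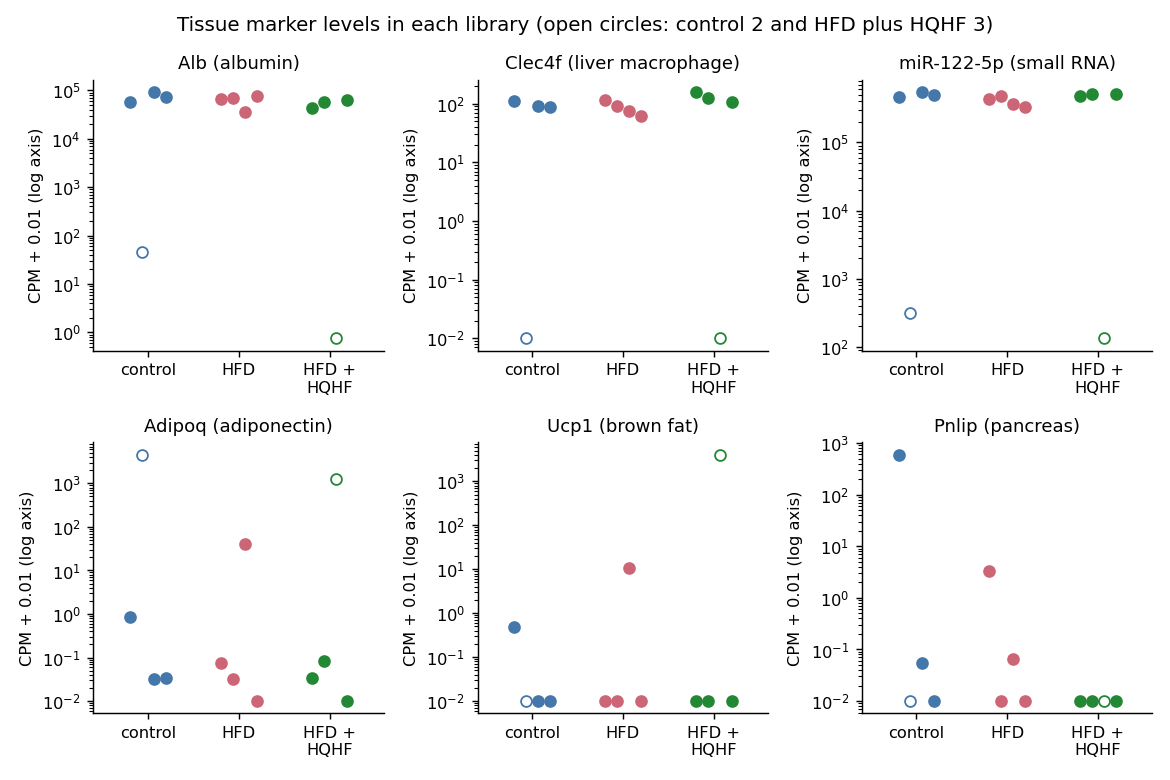
CPM by library totals, plus 0.01 on a log axis, of 5 genes in the long RNA libraries and of miR-122-5p in the small RNA libraries, with 1 circle per mouse (4 mice per group). Open circles mark control 2 and HFD plus HQHF 3, which held 46.4 and 0.743 CPM of Alb and 4543 and 1254 CPM of Adipoq.

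The first comparison asks what the high-fat diet did to gene expression in the liver. With all 12 mice, 7 genes were higher in HFD than in control, among them genes of monocyte-derived cells and a collagenase gene. Itgax (ENSMUSG00000030789), which encodes the integrin CD11c of monocyte-derived cells, was at 17.9 ± 7.08 CPM in HFD and 1.13 ± 0.374 CPM in control (SD, n = 4 each), a log2 fold change of 3.98 ± 0.36 (SE, adjusted p = 0.00322). Cx3cr1 (ENSMUSG00000052336), the fractalkine receptor of monocytes, rose from 0.679 ± 0.381 to 13.01 ± 8.05 CPM, a log2 fold change of 4.25 ± 0.57 (adjusted p = 0.0291). Mmp13 (ENSMUSG00000050578), a collagenase, rose from 0.0413 ± 0.0278 to 4.14 ± 2.74 CPM, a log2 fold change of 6.57 ± 0.79 (adjusted p = 0.0142). Sema4d (ENSMUSG00000021451), a semaphorin of immune cells, rose by 3.22 ± 0.36 on the log2 scale (adjusted p = 0.0118). The other genes called were Uap1l1 (ENSMUSG00000026956, 2.36 ± 0.27, adjusted p = 0.0118), the receptor gene Gpr35 (ENSMUSG00000026271, 2.36 ± 0.33, adjusted p = 0.0301) and Haus8 (ENSMUSG00000035439, 2.18 ± 0.27, adjusted p = 0.0142), a spindle protein gene that falls outside the naming rule and was chosen after its values were seen.

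No gene was lower among 13929 tested by edgeR with all 12 mice. In each of the 7 genes the groups did not overlap, as in 10.3% of all tested genes, where chance gives 2.86%. Unadjusted p was under 0.05 for 1855 genes, and DESeq2 called 659. Without control 2 the count was 106, and without control 1, control 3 or control 4 it was 1 each. Leaving out HFD 1 or HFD 4 left 4 genes.

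Of the 30 lists with at least 5 tested members, 8 were higher and 1 was lower in HFD than in control with all 12 mice. The monocyte and recruited macrophage list had 2 of 12 members up over all genes and 5 adjusted over the list alone (camera adjusted p = 3.6e-11). The neutrophil list followed with 0 of 7 members over all genes and 4 adjusted over the list alone (adjusted p = 2.1e-05), and its smallest-p members were Csf3r, at a log2 fold change of 1.55, and Mmp8, at 3.15. Higher as well were the lists for cell cycle (adjusted p = 5.05e-05, 0 of 20 members, 1 adjusted over the list alone), T and NK cells (0.000375, 0 of 12, 3 up and 1 down over the list alone), matrix and fibrosis (0.00125, 1 of 19 either way), interferon response (0.00156), cytokines and acute phase (0.00195) and stellate cells (0.0498). The last 3 lists had 0 members past the gene test either way. The mitochondrially encoded list was lower (adjusted p = 3.08e-07, 0 of 13 members, median log2 fold change of -1.16). None of the 30 lists was called with an estimated correlation, where the lowest adjusted p, that of the neutrophil list, was 0.0944. Values of the 2 members with the smallest p were 2.37 for Ccl5, 2.82 for Tnf, 1.57 for Usp18, 1.20 for Oas1a, 1.46 for Mcm2, 3.13 for Cdc20, 2.85 for Cd8a and 2.65 for Nkg7 on the log2 scale, none past the gene test over all genes.

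With the 10 mice that held hepatocyte RNA, the HFD livers showed higher macrophage and matrix genes and lower genes of hepatocyte metabolism. Mmp12 (ENSMUSG00000049723), the elastase of macrophages, was at 40.7 ± 12.5 CPM in HFD (SD, n = 4) and 0.313 ± 0.00515 CPM in control (n = 3), a log2 fold change of 7.01 ± 0.33 (SE, adjusted p = 4.22e-06). Gpnmb (ENSMUSG00000029816), a glycoprotein of lipid-laden macrophages, was at 114 ± 52.2 and 0.41 ± 0.44 CPM (log2 fold change 8.08 ± 0.87, adjusted p = 0.00146). Trem2 (ENSMUSG00000023992), a lipid-sensing receptor of macrophages, rose from 0.233 ± 0.088 to 8.97 ± 3.39 CPM (5.26 ± 0.47, adjusted p = 0.000447). Acsl1 (ENSMUSG00000018796), which activates fatty acids for oxidation and storage, fell from 3492 ± 816 to 527 ± 93.9 CPM (-2.73 ± 0.30, adjusted p = 0.000932). G6pc (ENSMUSG00000078650), the last enzyme of glucose output, fell from 655 ± 91.4 to 157 ± 33.1 CPM (-2.06 ± 0.21, adjusted p = 0.000646).

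Of 13832 genes tested with 10 mice, 2257 were higher and 1368 lower in HFD than in control, 3625 in all, of which 2085 differed at least 2-fold. The groups did not overlap in 3409 of them and in 36.7% of all tested genes, against a chance share of 5.71%. Unadjusted p was under 0.05 for 5656 genes. All 7 genes called with 12 mice were called here too. The split into higher and lower rested on the scaling: with library totals in place of TMM factors, 7041 genes were higher and 154 lower, 97.9% higher against 62.3%, and the median log2 fold change of all genes was 0.66 instead of 0.06, so changes are given relative to TMM. Without control 1, control 3 or control 4 the count was 1568, 1757 or 2078.

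Among immune and scar-forming cells, each of the 12 members of the monocyte and recruited macrophage list rose, over all genes and adjusted over the list alone (adjusted p = 2e-10, or 0.237 with an estimated correlation). In the matrix and fibrosis list 15 of 19 members rose, 16 adjusted over the list alone (adjusted p = 2.75e-07, or 0.323 with an estimated correlation). They included Mmp13, with a log2 fold change of 6.32, and the collagen genes Col1a1 at 4.61 and Col3a1 at 3.37, of which the last 2 were chosen after their values were seen. Timp1, an inhibitor of matrix proteases, had 553 reads in HFD and 1 in control, a ratio of 275 with a 95% counting interval of 49.2 to 10900. In the stellate cell list 7 of 12 members rose by either count (adjusted p = 0.00545, or 0.494 with an estimated correlation), among them Des at 1.37 and Cygb at 2.54. In the neutrophil list 6 of 8 rose, 8 adjusted over the list alone (adjusted p = 0.0012, or 0.237 with an estimated correlation), with Csf3r at 1.45 and Mmp8 at 2.71. In the T and NK cell list 3 of 12 rose by either count, among them Il7r at 3.07 and Cd8a at 2.6 (adjusted p = 0.0296, or 0.754 with an estimated correlation). The Kupffer cell list, for liver-resident macrophages, was not called (adjusted p = 0.513): C1qb rose by 0.82 and C1qc by 0.77, while Timd4, at -1.54, Cd163, at -2.06, Clec4f, at -0.76, and Folr2, at -0.71, fell, all 6 chosen after their values were seen. With library totals 6 of the 12 Kupffer members rose and 0 fell. Not called either were the lists for cholangiocytes (2 of 9 up, 6 adjusted over the list alone, adjusted p = 0.199), endothelial cells (0 of 12, adjusted p = 0.524), B and plasma cells (0 of 10, 0.355) and red blood cells (1 of 8 down, 0.745). With library totals 7, 5, 4 and 0 members of these 4 lists and 8 T and NK members rose, and 0 fell.

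Inflammatory and dividing-cell genes were higher as well. In the list of cytokines and acute phase genes 10 of 19 members rose by either count (adjusted p = 0.00329, or 0.534 with an estimated correlation), led by Cxcl1, which draws neutrophils, at 3.58 and Ccl2, which draws monocytes, at 3.78. In the interferon response list 9 of 18 rose, 12 adjusted over the list alone (adjusted p = 5.67e-05, or 0.237 with an estimated correlation), with Usp18 at 1.52 and Mx1 at 1.34. In the cell cycle list 8 of 20 rose, 13 adjusted over the list alone (adjusted p = 0.0012, or 0.631 with an estimated correlation), among them the replication helicase genes Mcm6 at 1.76 and Mcm2 at 1.43. With library totals the lists for cytokines (adjusted p = 0.178), cell cycle (0.0625) and T and NK cells (0.281) were no longer called, although 13 cytokine, 18 interferon and 19 cell cycle genes rose.

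Genes of fat burning, bile handling and detoxification were lower. In the list of fatty acid oxidation genes and targets of PPARA, the receptor that switches them on, 14 of 23 members fell, 17 adjusted over the list alone (median log2 fold change -1.16, adjusted p = 6.02e-10, or 0.354 with an estimated correlation). Cpt2, which brings fatty acids into the mitochondrial matrix, fell by 1.45 on the log2 scale. In the bile acid list 7 of 18 fell, 8 adjusted over the list alone (adjusted p = 9.62e-06, or 0.237 with an estimated correlation), among them Slc10a1, the bile acid uptake carrier, which fell from 502 ± 29.9 to 210 ± 32.5 CPM, and Baat at -1.19. In the xenobiotic metabolism list 11 of 19 fell and 2 rose by either count (adjusted p = 7.26e-06, or 0.237 with an estimated correlation). Ces2a, a carboxylesterase, fell from 431 ± 40.1 to 41.1 ± 22.0 CPM and Cyp3a25 by 1.78 on the log2 scale, while Cyp1a1 rose by 2.02 and Tiparp by 0.55, both targets of the aryl hydrocarbon receptor and chosen after their values were seen. In the hepatocyte list 6 of 16 fell, 8 adjusted over the list alone (adjusted p = 1.84e-06, or 0.237 with an estimated correlation), with Hpd, of tyrosine breakdown, at 1109 ± 64.5 against 3176 ± 430 CPM and Tdo2, of tryptophan breakdown, at -1.41. In the male-biased list 5 of 13 fell, 9 adjusted over the list alone (adjusted p = 1.09e-05, or 0.435 with an estimated correlation), with Cyp4a12b at -2.46 and Cyp2d9 at -2.30. In the mitochondrially encoded list 8 of 13 fell, 11 adjusted over the list alone (adjusted p = 7.26e-06, or 0.435 with an estimated correlation). Its members mt-Nd1 and mt-Co1 had log2 fold changes of -1.06 and -1.21, which were -0.44 and -0.58 and not past the test with library totals. In the glucose list 4 of 15 fell, 7 with 1 up adjusted over the list alone (adjusted p = 0.00482, or 0.435 with an estimated correlation), and its median of -0.34 turned to 0.25 with library totals. Irs2, of insulin signalling, was at -1.12 and not past the test with library totals, at -0.51. With library totals these lists were still called lower relative to other genes, but fewer members passed: 5 of the fatty acid oxidation list, 3 of the hepatocyte list, 4 of the male-biased and 0 of the mitochondrially encoded list fell with 0 rising. In the bile acid list 5 then fell and 1 rose, in the xenobiotic list 4 fell and 2 rose, and in the glucose list 1 fell and 3 rose.

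Cacna1h, Vmn2r3, AW551984, Lrrc55 and Bmp8b had no read in the 3 control libraries, so that HFD was at least 101-fold, 46.9-fold, 40.6-fold, 39.3-fold and 40-fold higher against 3 reads over the group. HFD 3 held most reads of Cacna1h and AW551984 and HFD 4 of Bmp8b, and without that library the bounds were 12.5, 14.1 and 19.7. The genes for major urinary proteins, which carry pheromones, were 5 of the 6 lowest by the naming rule: Mup15 at -7.21, Mup17 at -6.28, Mup7 at -5.68, Mup12 at -5.41 and Mup9 at -4.85, besides Ugt2b38 at -5.07. Mup genes are near-identical paralogs, so the counts of each one are uncertain.

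The labels tie the study to ferroptosis, cell death by iron-driven lipid peroxidation, and these lists were not called with either set of mice. With 12 mice 0 members of the driver, suppressor and iron lists passed the edgeR test over all genes. With 10 mice 7 of 23 drivers rose and 3 fell (adjusted p = 0.745), 2 of 26 suppressors rose and 4 fell (adjusted p = 0.298), and 3 of 25 iron handling genes rose and 5 fell (adjusted p = 0.269). With library totals 12 drivers, 12 suppressors and 9 iron genes rose and 0 fell, and the lists were still not called. The driver list had a median log2 fold change of -0.08, a mean of 0.27 and a camera direction of down, and library totals turned its median to 0.51. Slc7a11 (ENSMUSG00000027737), the cystine carrier that feeds glutathione synthesis, rose from 0.0344 ± 0.0391 to 3.04 ± 2.29 CPM with 10 mice (6.28 ± 1.01, adjusted p = 0.00383), and with 12 mice it was at 4.49 ± 1.29 (adjusted p = 0.202). Acsl4 (ENSMUSG00000031278), which loads membranes with polyunsaturated fatty acids, rose from 51.7 ± 11.9 to 85.5 ± 18.5 CPM (0.73 ± 0.24, adjusted p = 0.0441), and with 12 mice it was at 0.84 ± 0.32 (adjusted p = 0.299). Gpx4 (ENSMUSG00000075706), which reduces lipid peroxides, had log2 fold changes of 0.04 with 12 mice and 0.17 with 10 (adjusted p = 0.977 and 0.691), and of 0.82 and past the test with library totals. With 10 mice Hmox1 rose by 0.65, Cyb5r1 by 1.24 and Steap4 by 1.60, while Atg5, at -0.68, and Gch1, at -0.97, fell, neither past the test with library totals. Tfrc, the transferrin receptor, was at 1.20 with an SD of 37.8 CPM in HFD around a mean of 42.4 CPM (adjusted p = 0.128), and Fth1, of the iron store ferritin, was at 0.00, and both passed the test with library totals, at 1.79 and 0.61. Values for the ferritin receptor gene Ncoa4 and for Cisd1 with 12 mice were -0.88 and -0.87.

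Lipid synthesis and storage genes gave no list call with TMM. With 10 mice 2 of 20 lipogenesis genes rose and 1 fell (adjusted p = 0.494), 4 of 20 lipid uptake and droplet genes rose and 3 fell (0.685), and 0 of 24 cholesterol synthesis genes rose and 3 fell (0.0598). Cd36, a fatty acid carrier, rose by 1.34 with 10 mice (adjusted p = 0.0178) and was at -2.24 with 12 (adjusted p = 0.549), where control 2 alone held 5023 CPM. Fasn was at 2.09 with 10 mice (adjusted p = 0.103) and passed with library totals, at 2.66, and it was at 0.85 with 12. Scd1 was at -2.90 and -3.30 with 10 and 12 mice, Cpt1a at -0.91 and -0.56, and Cyp7a1, the first enzyme of bile acid synthesis, at -0.91 and -0.54, none past the test. The remaining lists not called with 10 mice were antioxidant and NRF2 targets (5 up, 3 down of 20, adjusted p = 0.793), ER stress (2 up, 1 down of 16, 0.494), circadian clock (4 up, 3 down of 20, 5 and 3 adjusted over the list alone, 0.745) and female-biased genes (1 up, 1 down of 10, 0.881). With library totals camera placed lipogenesis (adjusted p = 0.044), lipid uptake and droplets (0.00693), cholesterol synthesis (0.000122) and female-biased genes (0.0179) below other genes, although their medians were then 0.60, 0.85, 0.50 and 1.61 and 7, 5, 3 and 2 members rose, with 2 cholesterol genes falling. Then 8 antioxidant, 4 ER stress and 10 clock genes rose and 0 fell.

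**Figure D2:**
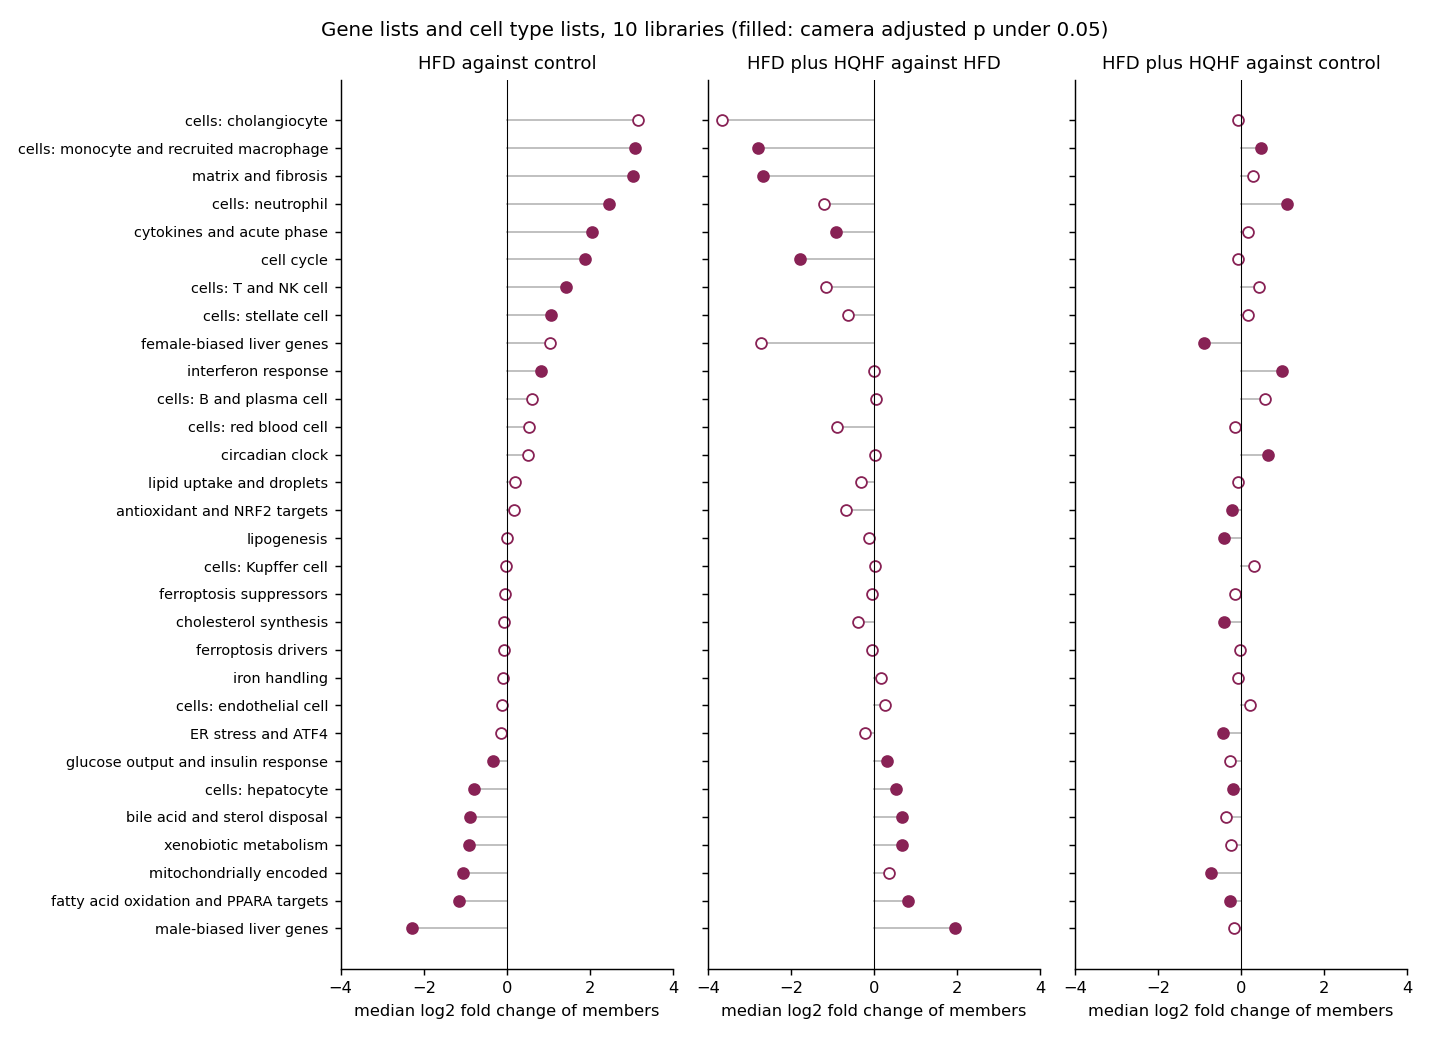
Median log2 fold change of the tested members of each of the 30 lists with 10 mice, scaled by TMM, in the 3 comparisons. Filled circles mark a camera adjusted p under 0.05; with library totals the median of the glucose list turned from -0.34 to 0.25 in HFD against control and from 0.31 to -0.25 in HFD plus HQHF against HFD, and that of the hepatocyte list from 0.53 to -0.02 in the latter.

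The small RNA libraries of the same mice answer the same question for miRNAs. With all 12 mice, miR-34a-5p, which is induced by the tumour suppressor p53, rose from 725 ± 187 to 2984 ± 970 CPM in HFD (SD, n = 4 each), a log2 fold change of 2.04 ± 0.29 (adjusted p = 0.00612). miR-582-3p rose from 1.18 ± 0.475 to 19.3 ± 9.41 CPM (3.99 ± 0.62, adjusted p = 0.00612). Its partner strand miR-582-5p, outside the naming rule for its low level and chosen after its values were seen, was at 4.54 ± 0.70 (adjusted p = 0.00612). These were the 3 called miRNAs of 414 tested by edgeR, with 0 lower, 68 at an unadjusted p under 0.05 and 21 by DESeq2. Without control 1 the count was 0, and without control 2 it was 17. None of the 6 miRNA lists was called with 12 mice (lowest adjusted p = 0.0739), though 1 was called without control 4 or HFD 2 and 3 without HFD 3.

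With 10 mice 31 miRNAs were higher and 35 lower among 406 tested, 66 in all, with no overlap in 65 of them and in 31.3% of all tested, against a chance share of 5.71%. All 3 miRNAs called with 12 mice were among them. miR-34a-5p was at 2585 ± 729 CPM in HFD (n = 4) and 558 ± 50.8 CPM in control (n = 3), a log2 fold change of 2.21 (adjusted p = 0.00534). miR-582-3p was at 4.20, miR-223-3p, a miRNA of myeloid cells, at 1.58, miR-674-5p at 1.40 and miR-674-3p at 1.30. The lowest were miR-592-5p at -2.42, miR-1948-5p at -1.90, miR-455-5p at -1.75 and the near-identical miR-1843a-5p and miR-1843b-5p at -1.52 and -1.51. miR-122-5p was at 325800 ± 116800 against 623000 ± 142200 CPM by TMM (-0.94, adjusted p = 0.046), a call that ended with library totals, at -0.31. miR-21a-5p was at -0.96 (adjusted p = 0.0694), and with 12 mice miR-122-5p was at -0.52 and miR-21a-5p at -0.61. The hepatocyte miRNA list had 4 of 9 members down, 6 adjusted over the list alone (adjusted p = 0.00754, or 0.67 with an estimated correlation). The immune cell miRNA list had 4 of 8 members up, 5 adjusted over the list alone (adjusted p = 0.0213, 0.67 with an estimated correlation and 0.0833 with library totals), among them miR-342-3p, miR-142a-5p and miR-150-5p besides miR-223-3p. The steatosis-linked, stellate, miR-200 and red blood cell lists were not called. With library totals 133 miRNAs were higher and 8 lower, 94.3% higher against 47%, and the median of all miRNAs was 0.74 instead of 0.13. Leaving out control 3, control 4, HFD 1 or HFD 4 left 14, 15, 31 or 27 miRNAs.

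The second comparison asks what HQHF changed in mice on the high-fat diet. With all 12 mice, Itgax fell by 3.58 ± 0.35 on the log2 scale, to 1.49 ± 0.219 CPM in HFD plus HQHF from 17.9 ± 7.08 CPM in HFD (SD, n = 4 each, adjusted p = 0.00775). It was the 1 gene called of 13929 tested by edgeR, where 0 were higher, 1659 had an unadjusted p under 0.05 and DESeq2 called 504. The groups did not overlap in Itgax, as in 10.5% of all tested genes, where chance gives 2.86%. Values that did not pass were -4.42 for Mmp13 (adjusted p = 0.0841), -1.77 for Cd9, a tetraspanin of scar-associated macrophages (0.0501), -5.96 for Slc7a11 (0.195), -1.32 for Acsl4 (0.195) and 2.11 for Acsl1 (0.243). Without HFD plus HQHF 2 or HFD plus HQHF 3 the count was 0, and without HFD plus HQHF 1 or HFD plus HQHF 4 it was 2.

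Of the 30 lists with 12 mice, 8 were lower and 2 higher in HFD plus HQHF than in HFD. The macrophage list had 1 of 12 members down, 4 adjusted over the list alone (adjusted p = 7.18e-11). Lower too were the lists for cell cycle (adjusted p = 6.28e-05), cytokines (0.000122), matrix (0.00021), cholangiocytes (0.00179), neutrophils (0.0116), T and NK cells (0.0288) and female-biased genes (0.0486), each with 0 members over all genes. Adjusted over the list alone, 1 cell cycle gene, 1 matrix gene, 6 of 8 cholangiocyte genes and 2 female-biased genes fell. Their smallest-p members included Krt7 at -4.39 and Muc1 at -4.23, with overlapping groups, and Cyp2a4. It had 3 reads in HFD plus HQHF and 7249 in HFD, a ratio of 1820 (interval 623 to 8840), or 180 without HFD 4. Higher were the mitochondrially encoded list (adjusted p = 0.000203) and the fatty acid oxidation list (0.00786), with 0 members over all genes. None was called with an estimated correlation (lowest adjusted p = 0.402).

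With 10 mice, the macrophage and matrix genes that were high in HFD were low in HFD plus HQHF, and some metabolic genes were higher. Mmp12 fell by 6.19 ± 0.31 on the log2 scale, to 0.552 ± 0.185 CPM in HFD plus HQHF (SD, n = 3) from 40.7 ± 12.5 CPM in HFD (n = 4, adjusted p = 8.2e-06). Gpnmb fell by 7.91 ± 0.86, to 0.467 ± 0.457 CPM (adjusted p = 0.0021), and Lgals3, the galectin of activated macrophages, by 3.03 ± 0.28 (adjusted p = 0.000623). Acsl1 rose by 2.08 ± 0.29, to 2231 ± 879 from 527 ± 93.9 CPM (adjusted p = 0.00352), and G6pc by 1.41 ± 0.21, to 417 ± 55.8 from 157 ± 33.1 CPM (adjusted p = 0.00387). Cyp2c29 (ENSMUSG00000003053), a detoxifying cytochrome P450, rose by 2.77 ± 0.36, to 685 ± 267 from 100 ± 39.6 CPM (adjusted p = 0.0027).

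Of 13832 genes tested, 1086 were higher and 1532 lower, 2618 in all, with 1453 differing at least 2-fold and 2463 without overlap, as were 30.7% of all tested, against a chance share of 5.71%. Unadjusted p was under 0.05 for 4999 genes. With library totals 137 were higher and 6496 lower, 2.07% higher against 41.5%, and the median of all genes was -0.62 instead of -0.07. The count was 1629 without HFD 1, 633 without HFD plus HQHF 1, 803 without HFD plus HQHF 2 and 1703 without HFD plus HQHF 4.

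In the macrophage list 11 of 12 members fell, 12 adjusted over the list alone (adjusted p = 1.86e-10, or 0.423 with an estimated correlation). In the matrix list 17 of 19 fell by either count, among them Mmp13 at -4.39 and Timp1 at -3.94 (adjusted p = 2.45e-08, or 0.434 with an estimated correlation). In the cell cycle list 8 of 20 fell, 17 adjusted over the list alone, with Mcm6 at -1.53 and Mcm2 at -1.20 (adjusted p = 0.00011, or 0.654 with an estimated correlation). In the cytokine list 5 of 19 fell, 7 adjusted over the list alone, with Ccl2 at -3.71 and Ccl3 at -3.85 (adjusted p = 0.0345, or 0.714 with an estimated correlation), a call that ended with library totals (adjusted p = 0.661). Not called were the lists for stellate cells (6 of 12 down, adjusted p = 0.0689), cholangiocytes (1 of 9 down, 7 adjusted over the list alone, 0.0689), T and NK cells (1 of 12 down, 0.201), neutrophils (0 of 8, 0.074), endothelial cells (1 of 12 up, 0.074, but 3 down with library totals), Kupffer cells (4 of 12 up, 5 adjusted over the list alone, 0.153, but 1 up and 4 down with library totals), B and plasma cells (0 of 10, 0.854) and red blood cells (1 of 8 up, 0.914, but 1 down with library totals). With library totals 19 cell cycle, 12 cytokine, 9 stellate, 8 cholangiocyte, 7 T and NK, 5 neutrophil and 3 B and plasma members fell and 0 rose.

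In the fatty acid oxidation list 7 of 23 members rose, 10 adjusted over the list alone (adjusted p = 7.62e-07, or 0.654 with an estimated correlation), with the peroxisomal thiolase gene Acaa1b at 1.53. In the bile acid list 7 of 18 rose, 10 adjusted over the list alone (adjusted p = 7.68e-05, or 0.434 with an estimated correlation). Slc10a1 was at 0.97 and the bile acid receptor gene Nr1h4 at 0.79, neither past the test with library totals, at 0.42 and 0.22. In the xenobiotic list 7 of 19 rose by either count, with Cyp3a25 at 1.53 beside Cyp2c29 (adjusted p = 8.17e-05, or 0.423 with an estimated correlation). In the male-biased list 2 of 13 rose, Cyp2d9 at 2.30 and Moxd1 at 10.15, and 8 adjusted over the list alone (adjusted p = 2.59e-05, or 0.654 with an estimated correlation). The level of Moxd1, 71.0 ± 101 CPM in HFD plus HQHF, overlapped that in HFD. In the hepatocyte list 4 of 16 rose, 5 adjusted over the list alone, with Hpd at 1.43 and Tdo2 at 0.95 (adjusted p = 9.52e-05, or 0.453 with an estimated correlation), and its median of 0.53 turned to -0.02 with library totals, where Tdo2, at 0.39, did not pass. In the glucose list 4 of 15 rose and 1 fell by either count (adjusted p = 0.0371, or 0.654 with an estimated correlation), and its median of 0.31 turned to -0.25 with library totals. Trib1, a regulator of lipid synthesis, was at 0.60 and did not pass with library totals, at 0.06. With library totals these 6 lists were still called higher relative to other genes, but fewer members passed: 2 rose and 1 fell in the fatty acid oxidation list, 1 and 1 in the bile acid list, 5 and 2 in the xenobiotic list, 1 and 2 in the glucose list, 1 and 0 in the hepatocyte list and 2 and 0 in the male-biased list. The mitochondrially encoded list was not called (0 of 13 members, adjusted p = 0.074). With library totals it was (adjusted p = 0.0121), as were the Kupffer cell (0.0151), circadian clock (0.00803) and lipid uptake lists (0.0404), each placed above other genes although their medians were then -0.16, -0.51, -0.50 and -0.90.

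The 6 highest genes by the naming rule with 10 mice, which leaves out overlapping groups, were major urinary protein genes, with shared reads: Mup15 at 8.30, Mup17 at 7.36, Mup7 at 6.40, Mup9 at 5.70, Mup12 at 5.46 and Mup2 at 5.25. Cyp2a4, whose reads can be shared with its paralogs, had 3 reads in HFD plus HQHF and 7249 in HFD, a ratio of 1230 with an interval of 422 to 5980, or of 121 without HFD 4. Fbn2 had 2 reads against 1144, a ratio of 292 with an interval of 80.6 to 2410, or of 33 without HFD 4. Eef1a2 and Vmn2r3 had no read in the 3 HFD plus HQHF libraries and were at least 60.7-fold and 48.1-fold lower, the first 13.1-fold without HFD 3.

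Ferroptosis and iron genes again gave no list call, with 0 members over all genes by edgeR with 12 mice. With 10 mice 2 of 23 drivers rose and 4 fell, 5 and 6 adjusted over the list alone (adjusted p = 0.865), 5 of 26 suppressors rose and 2 fell, 5 and 5 adjusted over the list alone (0.746), and 3 of 25 iron handling genes rose and 3 fell (0.392). With library totals 0, 1 and 0 rose and 12, 11 and 9 fell. Slc7a11 had 1 read in HFD plus HQHF and 669 in HFD, a ratio of 341 in favour of HFD with an interval of 61.1 to 13500. Acsl4 fell by 1.18 ± 0.24, to 37.7 ± 10.5 CPM (adjusted p = 0.0115). Hmox1, at -0.84, Steap4, at -1.44, and the iron carrier gene Slc11a2, at -1.13, fell, while Gch1 rose by 1.20 and Atg5 by 0.73, the latter not past the test with library totals, at 0.18. Gpx4 was at 0.20 with 12 mice and -0.10 with 10, neither past the test. Tfrc was at -1.43 (adjusted p = 0.0936) and Fth1 at -0.14 with 10 mice, and both passed with library totals, at -1.96 and -0.67.

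Lipid genes moved singly. Cd36 fell by 1.43 with 10 mice (adjusted p = 0.0186) and was at 1.15 with 12 (adjusted p = 0.845). Fasn was at -2.74 (adjusted p = 0.0595), past the test with library totals, at -3.25, and at 0.23 with 12 mice. Scd1 was at -0.10, Cpt1a at 0.80 and Cyp7a1 at 0.42 with 10 mice, none past the test. The lists not called were lipogenesis (1 up, 2 down of 20), lipid uptake and droplets (1 up, 4 down of 20), cholesterol synthesis (2 up of 24), antioxidant and NRF2 targets (3 up, 6 down of 20), ER stress (3 down of 16), interferon response (0 of 18, adjusted p = 0.406), circadian clock (2 up of 20, 0.201) and female-biased genes (2 down of 10). With library totals 0 members of these 8 lists rose, and 8, 5, 9, 10, 7, 6, 2 and 5 fell.

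**Figure D3:**
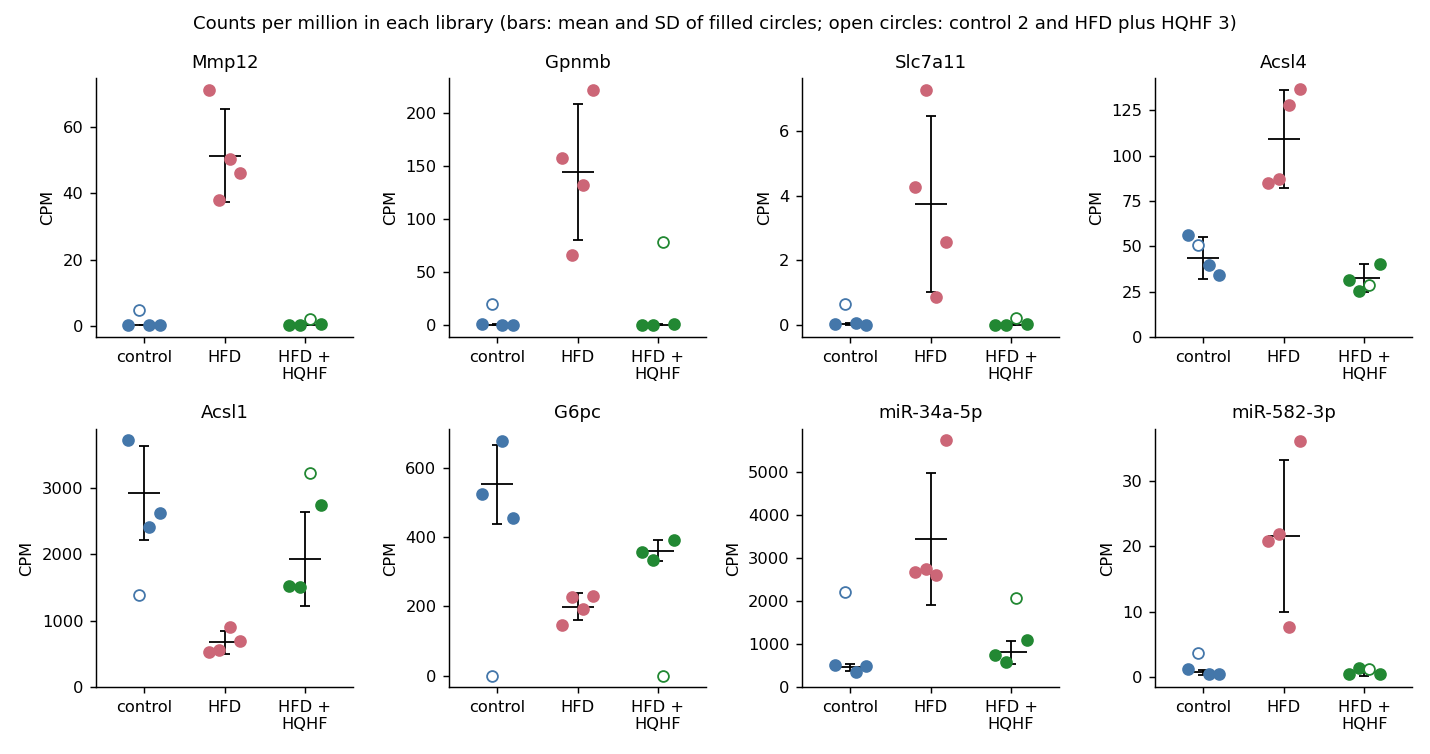
CPM by library totals of 6 genes and 2 miRNAs, with 1 circle per mouse and bars for the mean and SD of the filled circles. Means in the text are by TMM. Open circles mark control 2 and HFD plus HQHF 3; the 4 HFD mice lie above the filled circles of both other groups for Mmp12, Gpnmb, Slc7a11, Acsl4, miR-34a-5p and miR-582-3p, and below them for Acsl1 and G6pc.

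Among miRNAs with 12 mice, miR-582-3p fell by 4.19 on the log2 scale (adjusted p = 0.0131) and miR-582-5p by 3.93 (adjusted p = 0.0242), the latter chosen after its values were seen. miR-34a-5p was at -1.44 (adjusted p = 0.054). These were the 2 called of 414 tested by edgeR, with 0 higher, 71 at an unadjusted p under 0.05 and 34 by DESeq2. Each of HFD 2, HFD 4, HFD plus HQHF 1 and HFD plus HQHF 4 left 0 when taken out, HFD 1 and HFD plus HQHF 2 left 1 each, and without HFD 3 there were 4. The immune cell miRNA list (adjusted p = 0.0429) and the miR-200 family, of epithelial cells (0.0196), were lower with 12 mice (adjusted p = 0.391 for both with an estimated correlation).

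With 10 mice 43 miRNAs were higher and 38 lower, 81 in all, with no overlap in 77 and in 38.2% of all tested, against a chance share of 5.71%. The highest were miR-3065-5p at 2.46, miR-192-3p at 1.64, miR-551b-3p at 1.46, miR-33-5p, which lies within the sterol regulator gene Srebf2, at 1.16 and miR-192-5p, of hepatocytes, at 1.14. The calls of miR-3065-5p and miR-33-5p ended with library totals, at 1.92 and 0.58. The lowest were miR-582-3p at -4.08, miR-218-5p at -3.99, miR-200c-3p at -3.90, miR-133a-3p at -3.54 and miR-205-5p at -3.27. The groups overlapped in miR-3065-5p, miR-200c-3p and miR-205-5p. miR-34a-5p fell to 936 ± 307 CPM (-1.47, adjusted p = 0.0143), and miR-122-5p, at 0.83 (adjusted p = 0.0541), and miR-21a-5p, at 0.29, did not pass. With 12 mice miR-122-5p was at 0.46 and miR-21a-5p at -0.05. The hepatocyte miRNA list had 4 of 9 members up, 5 adjusted over the list alone (adjusted p = 0.00755, or 0.587 with an estimated correlation), and the immune cell list 4 of 8 down, 6 adjusted over the list alone (adjusted p = 0.00961, or 0.587 with an estimated correlation). The other 4 miRNA lists were not called. With library totals 7 miRNAs were higher and 140 lower, 4.76% higher against 53.1%, and the median of all miRNAs was -0.72 instead of -0.13. Leaving out HFD 1, HFD plus HQHF 1, HFD plus HQHF 2 or HFD plus HQHF 4 left 17, 3, 4 or 9 miRNAs.

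The third comparison asks what still differed from the normal diet under HQHF. With 12 mice the interferon response list was higher in HFD plus HQHF than in control (median log2 fold change 0.78, 0 of 18 members over all genes and 1 adjusted over the list alone, adjusted p = 4.22e-07, or 0.128 with an estimated correlation), as was the circadian clock list (0.81, adjusted p = 7.14e-05, or 0.111 with an estimated correlation). Of the 20 clock members 8 were up and 1 was down adjusted over the list alone, and 0 over all genes. Dbp (ENSMUSG00000059824), a transcription factor under clock control, was at 30.4 ± 19.0 against 2.08 ± 1.22 CPM (SD, n = 4 each, 3.87, adjusted p = 0.933). No gene was called by edgeR among 13929, with 660 at an unadjusted p under 0.05 and 3 called by DESeq2. Besides Dbp the smallest p values were those of Srsf2 at -0.75, Tsc22d2 at -0.74, Sltm at -0.78 and Sfpq at -0.80. Also higher were the lists for neutrophils (adjusted p = 0.00235) and T and NK cells (0.0499), and lower those for ER stress (0.0332), mitochondrially encoded genes (0.0424) and female-biased genes (0.0499), 7 lists in all, none of them called with an estimated correlation. The 12-mouse list count was 17 without control 2 and 3 without control 4.

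With 10 mice the interferon list was again higher (0.98, 0 of 18 members over all genes, 12 adjusted over the list alone, adjusted p = 3.86e-15, or 0.0571 with an estimated correlation). Its members Mx1, an antiviral GTPase, and Ifit3 were at 1.95 and 1.25, not past the test over all genes. No gene was called by edgeR among 13832, with 1008 at an unadjusted p under 0.05 and 72 called by DESeq2. The smallest adjusted p, 0.228, belonged to Zbtb48 at 1.45, Mx1, Tmem64 at -0.76, Tbc1d10a at 1.17 and Ccl21b, which had no read in control, was at least 13.3-fold higher and shares reads with its paralogs. Higher too were the lists for neutrophils (1.11, adjusted p = 0.00187, or 0.432 with an estimated correlation), macrophages (0.49, 0.0172, 1 member adjusted over the list alone), with Trem2 at 1.94, and the clock (0.65, 0.0207, 8 up and 1 down adjusted over the list alone), with Dbp at 3.95 and Bhlhe41 at 2.73. Neither of the last 2 was called with an estimated correlation (adjusted p = 0.593 and 0.432). Lower were the lists for mitochondrially encoded genes (-0.73, adjusted p = 1.57e-07, or 0.593 with an estimated correlation), fatty acid oxidation (-0.27, 0.000559), with Pdk4, a brake on glucose oxidation, at 17.8 ± 2.58 against 94.3 ± 18.8 CPM, and cholesterol synthesis (-0.42, 0.00173), the last 2 not called with an estimated correlation (adjusted p = 0.593 and 0.599). Lower as well were lipogenesis (-0.41, 0.0172), with Scd1 at -3.00, hepatocyte genes (-0.20, 0.0172), antioxidant genes (-0.22, 0.0207), ER stress (-0.44, 0.0261), with the chaperone gene Hspa5 at -1.11, and female-biased genes (-0.90, 0.0345), none of them called with an estimated correlation (adjusted p = 0.593 for each). In all 12 lists 0 members passed over all genes. With library totals the lists for bile acids (adjusted p = 0.0212), glucose (0.0213) and xenobiotics (0.0179) were called lower too, and those for endothelial (0.0339), stellate (0.0496) and B and plasma cells (0.0497) higher. Without control 4 the count of lists was 5. Ferroptosis and iron lists were not called with 12 or 10 mice, and with 10 mice Gpx4 was at 0.07, Acsl4 at -0.46, Hmox1 at -0.19, Tfrc at -0.23, Fth1 at -0.14, Cd36 at -0.09 and Fasn at -0.65, none past the test.

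Among miRNAs none was called with 12 mice by edgeR (79 at an unadjusted p under 0.05, 22 by DESeq2), where the smallest adjusted p was 0.142, for miR-484, miR-132-5p, miR-674-5p, miR-181d-5p and miR-1198-5p. With 10 mice miR-574-3p at 1.24, miR-674-5p at 1.15 and miR-350-3p at 0.98 were higher and miR-484 at -1.38 and miR-132-5p at -2.23 were lower, the last outside the naming rule and chosen after its values were seen. The groups did not overlap in these 5, as in 44.6% of all tested miRNAs, where chance gives 10%. Leaving out any 1 of the 6 mice, or scaling by library totals, left 0 called. miR-34a-5p was at 0.60 with 12 mice and 0.75 with 10, miR-122-5p at -0.06 and -0.11, and miR-21a-5p at -0.66 and -0.67, none past the test. No miRNA list was called with 12 (lowest adjusted p = 0.499) or 10 mice (0.752).

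Whether the genes that the diet changed moved back under HQHF was asked with the share of genes called in HFD against control that had the opposite sign in HFD plus HQHF against HFD. With 12 mice these were 7 of 7 genes (100%, Clopper-Pearson 95% interval 59.0% to 100%), beside 75.1% of all tested genes. The shared HFD libraries alone give opposite signs. In 20 simulations with HQHF at the HFD means, the median and highest shares of called genes (median 205 called) were 73.7% and 79.2%. Simulated ranges and intervals took genes as independent, without the variation shared within a mouse, so both are too narrow. For all genes these shares were 60.4% and 61.2%. With control at the HFD means too, called genes gave 100% (median 0 called) and all genes 66.8% and 67.5%. So 7 of 7 cannot show a move back. With 10 mice 3570 of 3625 genes moved back (98.5%, 98.0% to 98.9%), against a simulated median of 59.8% and a highest value of 61.9%. Among all tested genes 82.9% moved back, against 55.1% and 56.0%, or 63.9% and 64.7% with control at the HFD means too. The correlation of the fold changes across genes, which are not independent replicates, was -0.868, against simulated medians of -0.142 and, with control at the HFD means too, -0.417 (lowest -0.451), and the covariance was -1.01, against -0.0679 and -0.0683. When separate HFD mice served each comparison, 87.1% to 98.8% of the called genes moved back with 10 mice and the covariance ran from -0.728 to -0.995. In all 1274 genes rose with the diet and fell with HQHF, 768 fell and then rose, and 0 were called in the same direction in both. The simulations gave at most 1 and 0, but with HQHF at the HFD means almost no gene can be called in the second comparison. Their counts therefore cannot show how much overlap the shared HFD mice give. Independent lists, which leave out the shared HFD mice, would give 250 and 107 (n1 × n2 / N). With separate HFD mice the overlaps were 254 to 698 and 92 to 378, against 47.1 to 173 and 7.69 to 78. Acsl1, G6pc, Mmp12, Gpnmb and Acsl4 were among those called in opposite directions.

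**Figure D4:**
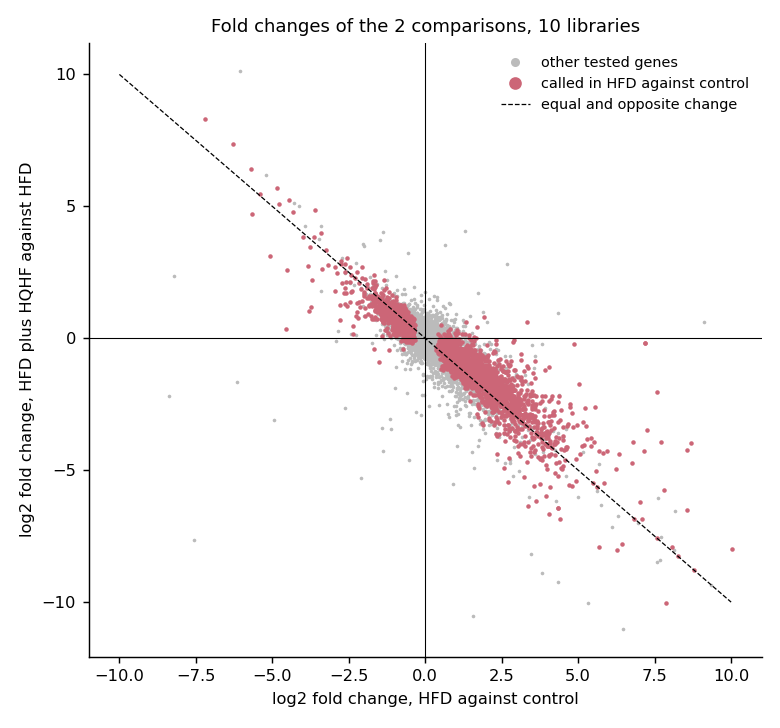
Log2 fold change of each tested gene in HFD against control (x axis) and in HFD plus HQHF against HFD (y axis) with 10 mice, scaled by TMM. Red points are the 3625 genes called in HFD against control, of which 3570 have the opposite sign on the y axis; the dashed line marks equal and opposite changes.

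Library summaries were compared between groups by exact two-sided permutation tests, 39 per set of mice, and none passed after adjustment. With 10 mice, genes detected numbered 16150 ± 267 in HFD (n = 4) against 15070 ± 178 in control and 15160 ± 78.6 in HFD plus HQHF (n = 3 each, exact p = 0.0286 for both, adjusted p = 0.202). The gene Nemf took 1.97% to 13.3% of long RNA counts, with 9.83 ± 2.86% in HFD plus HQHF against 5.84 ± 0.481% in HFD (exact p = 0.0286, adjusted p = 0.202). The smallest p that these tests can give is 0.0286 for 4 against 4 or 4 against 3 mice, and 0.1 for 3 against 3.

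Red blood cell RNAs served to check that the long and small RNA libraries of a mouse belong together. Over 12 mice Hbb-bs, the beta globin gene, and miR-451a, a miRNA of red blood cells, had a Pearson r of 0.66 (permutation p = 0.0305, adjusted p = 0.061) and a Spearman rho of 0.42 (permutation p = 0.177, adjusted p = 0.307). Without control 2 and HFD 4, the mice farthest from the median, r was 0.55 (permutation p = 0.0962), and over the 10 mice with hepatocyte RNA it was -0.0679 (permutation p = 0.888). No value passed after adjustment, and r was near 0 without control 2 and HFD plus HQHF 3. Within groups r was 0.70 (permutation p = 0.0168, adjusted p = 0.061).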

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

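The tests of explanations and of other splits of the mice in this part were chosen after the results were seen. Within each group of 4 libraries, the gap between the highest or lowest library and its neighbour was divided by the whole range, and 56 of 177 such groups exceeded Dixon's 95% critical value, where chance gives about 9. Of these, 21 were due to control 2, 27 to HFD plus HQHF 3 and 8 to other libraries.

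In control 2 the ratio was 0.99 for the hepatocyte list, 0.99 for bile acid, 0.97 for xenobiotic metabolism, 0.93 for fatty acid oxidation, 0.91 for glucose output, 0.84 for male-biased and 0.83 for cholesterol synthesis genes. It was 0.99 for interferon, 0.97 for matrix, 0.97 for neutrophil, 0.96 for adipocyte, 0.91 for cell cycle and 0.9 for macrophage genes, all on the high side. Single genes gave 1 for Cd36 (5023 CPM against a next value of 72.0 CPM), 0.95 for Fasn, 0.9 for Slc7a11 and 0.83 for Scd1. In small RNA the ratio was 0.95 for the hepatocyte miRNA list, 0.85 for miR-122-5p, 0.91 for miR-34a-5p (2202 against 520 CPM) and 0.87 for the number of miRNAs detected (893 against 699).

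In HFD plus HQHF 3 the ratio was 0.96 for the hepatocyte list, 0.97 for bile acid, 0.92 for xenobiotic metabolism, 0.87 for male-biased, 0.83 for glucose output and 0.83 for stellate cell genes, all on the low side. It was 0.97 for macrophage, 0.92 for adipocyte, 0.92 for lipid uptake, 0.9 for cell cycle and 0.87 for matrix genes on the high side, and 0.87 for iron handling genes. Single genes gave 0.98 for Fasn, 0.97 for Cd36, 0.91 for Scd1, 0.9 for Hmox1, 0.9 for Slc7a11 and 0.87 for Gpx4 (710 against 255 CPM). In small RNA the ratio was 0.98 for the hepatocyte and 0.94 for the miR-200 list on the low side, and 0.99 for the steatosis-linked, 0.88 for the stellate, 0.87 for the immune and 0.84 for the red blood cell list on the high side. It was 0.95 for miR-122-5p, 0.92 for miRNAs detected (835 against 676) and 0.91 for the share of the 10 most abundant miRNAs.

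Among other libraries, HFD 3 had a ratio of 0.84 for the share of the 10 most abundant genes and 0.87 for the mitochondrial share. HFD 4 had 0.93 for Tfrc (124 against 32.8 CPM), 0.88 for the clock list and 0.96 for miR-34a-5p (5731 against 2739 CPM). HFD 1 had 0.86 for its small RNA total and 0.86 for the acinar list (score 1.77 against 0.427), and control 1 had 1 for the acinar list (score 7.55 against 0.254).

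The first pattern is that control 2 and HFD plus HQHF 3 stand apart. Liver RNA with some fat RNA added is argued against, since the median hepatocyte gene was at 0.0127% or less of its level in the other 10 libraries and the highest at 0.27%. A loss of hepatocytes alone within liver is argued against. It would not add fat RNA, but 8 of 8 adipocyte genes lay above the other 10 libraries in each. The Kupffer list could not decide, with 4 of 12 genes below all other libraries in both. RNA of another tissue in both library preparations is a candidate explanation, given the adipocyte genes and miR-122-5p at 0.0947% or less of the lowest other small RNA library. The labels call all samples liver, and the design names no biological difference that sets these mice apart.

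The second pattern is the lower hepatocyte and higher macrophage and matrix genes of HFD against control in 10 mice. A lower share of hepatocyte RNA alone would raise the other cell types alike. But their shifts ran from -0.27 for Kupffer and 0.00 for endothelial cells to 3.62 for macrophage lists. Their SD was 1.23, against at most 1.1 in other assignments (exact permutation p = 0.0286, the smallest possible). The macrophage minus hepatocyte score within a library, which no scaling moves, was 4.47 higher in HFD on the log2 scale (exact p = 0.0286). It was -3.68 in HFD plus HQHF against HFD. This argues against scaling for the gap but cannot decide for lower hepatocyte genes, as macrophage genes shifted by 3.62. Traces of fat RNA in HFD 3 or acinar RNA in control 1 are argued against, as 15 of 15 lists were called the same way without either. A change of cell makeup, of expression within cells, or of both under the diet stays open, since bulk RNA does not separate these.

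The third pattern is that clock genes lay apart between HFD and control in 10 mice, with Dbp at 3.31, Bhlhe41 at 2.88, Ciart at 2.32 and Bhlhe40 at 2.02, and Nfil3 at -1.40, Hlf at -0.82 and Clock at -0.53. Scaling is not excluded: with library totals 10 clock genes were higher and 0 lower over all genes, and the spread between the 20 genes' shifts, which a common shift does not move, had an SD of 1.26 against up to 1.33 in other assignments (exact permutation p = 0.0571). Collection at another time of day cannot be told apart from an effect of the diet: the 11 genes that peak with Dbp minus the 5 that peak with Bmal1 were 1.93 higher on the log2 scale (exact p = 0.0857). In HFD plus HQHF against control the difference was 2.43 (exact p = 0.1, the smallest possible). The labels give no time of collection.

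Other splits of the same mice were fitted to see whether chance can be excluded. The smallest share that 35 splits can give is 1 of 35. Each comparison was judged on its own, so a share of 1 of 35 does not by itself exclude chance. For genes with 12 mice, 1 of 35 splits, the real one, gave as many calls in HFD against control (7, highest other 0). In HFD plus HQHF against HFD it was 1 of 35 as well (1, highest other 0), and in HFD plus HQHF against control 35 of 35 gave 0. With 10 mice it was 1 of 35 (3625, highest other 1277) and 1 of 35 (2618, highest other 1313). The highest other splits parted control 1, 3, 4 and HFD 3, and HFD 1, 2 and 4, from the rest. For gene lists chance is not excluded: with 12 mice 29, 27 and 19 of 35 splits called as many (9, 10 and 7, highest other 16, 20 and 14), and with 10 mice 15 and 30 of 35 (15 and 10, highest other 19 and 19). For miRNAs with 12 mice 1 of 35 splits called as many in each of the first 2 comparisons (3 and 2, highest other 0 and 0) and 35 of 35 in the third (0, highest other 4). With 10 mice it was 1 of 35 in each (66 and 81, highest other 16 and 42). For miRNA lists 35, 17 and 35 of 35 splits called as many with 12 mice (0, 2 and 0, highest other 4, 3 and 2) and 18 and 14 of 35 with 10 (2 and 2, highest other 4 and 4), so chance is not excluded. HFD plus HQHF against control in 10 mice has 10 splits, too few for a share under 0.05: 10 gave 0 genes (highest other 0), 1 gave 12 gene lists (highest other 10), 1 gave 5 miRNAs (highest other 0) and 10 gave 0 miRNA lists (highest other 1).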

How the results depend on the processing

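All tests with 10 mice and with library totals were chosen after the results were seen, whereas the other settings were fixed beforehand. Only the 12-mouse counts of genes, lists, miRNAs and miRNA lists were designed, so each count was fitted on 2 sets of libraries. The cause of a moved value was not tested unless the setting's own construction (fewer mice, a looser or stricter threshold) gives it. RLE scaling kept the counts of genes, miRNAs and lists within 1.5 times, with 12 and with 10 mice. Over the named genes, 1387 of 1559 values with 12 mice kept direction and side of the threshold, 37 fell below it, 76 rose past it, 57 without a call moved and 2 reversed: Cd36, with 10 mice, at 1.34 in HFD against control and -1.43 in HFD plus HQHF against HFD. With 10 mice 1791 of 2084 were kept, 238 fell below, 34 rose past, 20 moved and 1 reversed, Fth1 at 0.61 in HFD against control with library totals.

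Genes with 12 mice numbered 7, 1 and 0 in the 3 comparisons (HFD against control, HFD plus HQHF against HFD, HFD plus HQHF against control). DESeq2 called 659, 504 and 3, though it also made more false calls on simulated data, and 10 mice gave 3625 and 2618. An adjusted p under 0.1 gave 23 and 9, a filter of 1 CPM in 4 libraries gave 6 in the second, and only the libraries of the 2 groups compared gave 2 in the second. With the replicate number as a block (replicate block) 1 and 0 genes were called. Numbers showed no clear pairing: with 10 mice same-number residual correlations ran from -0.0542 to 0.119, over 0.1 in 1 of 8 pairs. Leaving out 1 library gave 1 to 106 in the first (1 without control 1, control 3 or control 4, 106 without control 2, 4 without HFD 1 or HFD 4), 0 to 2 in the second (0 without HFD plus HQHF 2 or 3, 2 without HFD plus HQHF 1 or 4) and 0 in the third.

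Genes with 10 mice numbered 3625, 2618 and 0. Library totals gave 7195 and 6633, a 2-fold minimum 2085 and 1453, an adjusted p under 0.1 4210 in the second, the replicate block 1719 in the second, only the 2 groups compared 1 in the third and DESeq2 72 in the third. Leaving out 1 library gave 1568 to 3882 (1568, 1757 and 2078 without control 1, 3 and 4), 633 to 3301 (633, 803, 1629 and 1703 without HFD plus HQHF 1, HFD plus HQHF 2, HFD 1 and HFD plus HQHF 4) and 0.

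Gene lists called with 12 mice numbered 9, 10 and 7. An estimated correlation gave 0, 0 and 0, fry gave 3, 1 and 0, and 10 mice gave 15 in the first and 12 in the third. Leaving out 1 library gave 8 to 13, 7 to 13 and 3 to 17 (17 without control 2, 3 without control 4). With 10 mice they numbered 15, 10 and 12, an estimated correlation gave 0, 0 and 0, fry gave 5 in the second and 1 in the third, and leaving out 1 library gave 15 to 16, 9 to 13 and 5 to 16 (5 without control 4). With 12 mice and library totals the calls of the matrix (adjusted p = 0.0765) and stellate lists (0.0856) in the first, the female-biased list (0.251) in the second and the mitochondrially encoded list (0.0535) in the third ended. Newly called in the first were fatty acid oxidation (0.000108), lipid uptake (0.00108), male-biased (0.00108), xenobiotic (0.0408) and red blood cell lists (0.0347) as lower and B and plasma cells (0.00887) as higher. In the second they were lipid uptake (0.000516), male-biased (0.00265) and clock (0.0256) as higher and antioxidant (0.0464) and ER stress (0.0464) as lower, and in the third cholesterol synthesis (0.0264) as lower and B and plasma cells (0.00204) as higher.

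miRNAs with 12 mice numbered 3, 2 and 0. DESeq2 gave 21, 34 and 22, 10 mice 66, 81 and 5, an adjusted p under 0.1 5 and 4, and only the 2 groups compared 0 in the second. Leaving out 1 library gave 0 to 17 (0 without control 1, 17 without control 2), 0 to 4 (0 without HFD 2, HFD 4, HFD plus HQHF 1 or HFD plus HQHF 4, 1 without HFD 1 or HFD plus HQHF 2, 4 without HFD 3) and 0. miRNA lists numbered 0, 2 and 0, with 2 in the first for 10 mice, 0 in the second with an estimated correlation or fry, 1 in the second with the replicate block, and 0 to 3, 0 to 2 and 0 when 1 library was left out (1 in the first without control 4 or HFD 2, 3 without HFD 3).

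With 10 mice miRNAs numbered 66, 81 and 5. No filter gave 26, 25 and 0, library totals 141, 147 and 0, only the 2 groups compared 19, 40 and 112, DESeq2 105, 124 and 57, an adjusted p under 0.1 123, 158 and 54, a 2-fold minimum 31 and 46, and the replicate block 37 in the first and 0 in the third. Leaving out 1 library gave 14 to 75 (14, 15, 31 and 27 without control 3, control 4, HFD 1 and HFD 4), 3 to 107 (3, 4, 9 and 17 without HFD plus HQHF 1, 2 and 4 and HFD 1) and 0 for each of the 6 in the third. miRNA lists numbered 2, 2 and 0: an estimated correlation gave 0 and 0, fry 1 in the first, only the 2 groups compared 1 in the third, and leaving out 1 library 2 to 3, 2 to 3 and 0.

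The share of called genes moving back stayed at 100% with 12 mice when 1 library was left out. With 10 mice it was 96.3% to 99.4% then, 82.9% over all tested genes, and 93.9%, 97.0%, 93.4% and 87.1% in 4 of the 6 choices of separate HFD mice. The correlation of Hbb-bs with miR-451a was 0.55 without the mice farthest from the median and -0.0679 with 10 mice. Depth limits genes with few reads: those with 3 reads or fewer in a group have only a bound or a wide interval.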

Other observations

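The tests in this part, on terms of the annotation that the authors deposited beside the counts, were chosen after the results were seen and used the 10 mice with hepatocyte RNA. Of 173 KEGG pathway terms with 10 to 500 members, camera called 21 higher and 29 lower in HFD than in control, 20 higher and 18 lower in HFD plus HQHF than in HFD, and 5 higher and 14 lower in HFD plus HQHF than in control, and 0 with an estimated correlation. The term named Thermogenesis, whose members are mostly subunits of the respiratory chain, had 62 of 124 members lower and 3 higher in HFD than in control (adjusted p = 1.4e-14, or 0.409 with an estimated correlation), and 42 higher and 2 lower in HFD plus HQHF than in HFD (adjusted p = 1.02e-12, or 0.512 with an estimated correlation), whereas with library totals 2 were lower and 11 higher (median log2 fold change -0.018), then 1 higher and 10 lower (-0.046). Peroxisome genes, of the organelle that shortens very long fatty acids, were lower in 32 and higher in 1 of 57 (adjusted p = 7.41e-11, or 0.279 with an estimated correlation), then higher in 30 and lower in 1 (1.02e-12, or adjusted p = 0.318 with an estimated correlation), though with library totals 5 were lower and 9 higher, then 8 higher and 4 lower. Proteasome genes, which degrade tagged proteins, were lower in 28 of 45 (adjusted p = 1.45e-08, or 0.373 with an estimated correlation), then higher in 15 (5.59e-09, or adjusted p = 0.512 with an estimated correlation), which turned with library totals to 6 higher and 0 lower, then 2 lower. These member counts are thus relative to TMM scaling, and camera was not run on the terms with library totals.

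Genes for cytokine and receptor interaction were higher in 40 and lower in 4 of 102 in HFD than in control (adjusted p = 1.11e-06, or 0.373 with an estimated correlation), then lower in 25 and higher in 4 (0.000224, or adjusted p = 0.512 with an estimated correlation). Complement and coagulation genes, secreted mainly by hepatocytes, were lower in 13 and higher in 1 of 27 (adjusted p = 4.22e-05), then higher in 11 and lower in 1 (8.7e-05), and their median log2 fold changes of -0.46 and 0.55 were 0.12 and about 0 with library totals. Genes that break down valine, leucine and isoleucine were lower in 11 and higher in 3 of 19 (adjusted p = 0.000344), then higher in 11 and lower in 2 (5.17e-05), but with library totals 1 was lower and 4 higher, then 1 higher and 2 lower. Motor protein genes were higher in 32 and lower in 4 of 136 (adjusted p = 0.000641), then lower in 29 and higher in 2 (0.000141). Ribosome genes were higher in 17 of 132 in HFD plus HQHF than in HFD (adjusted p = 2.47e-06), but with library totals 0 were higher and 9 lower. None of these 5 terms was called with an estimated correlation, where the lowest adjusted p was 0.372 in HFD against control and 0.373 in HFD plus HQHF against HFD among them.

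Some single values of the libraries stood out without a test. In the small RNA libraries of the 2 mice without hepatocyte RNA, miR-126a-3p, of endothelial cells, was at 104510 CPM in control 2 and 228560 CPM in HFD plus HQHF 3, against 23985 to 59847 CPM in the other 10. Control 2 held 57.6 CPM of Msln and 75.4 CPM of Upk3b, genes of mesothelium. HFD 4 held 1627 CPM of Hbb-bs.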
